A study of Drosophila melanogaster with 6 samples.

How the data were processed

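RNA of wing imaginal discs of the third larval instar, epithelia that form the adult wing and notum, was measured on 6 Affymetrix arrays of Drosophila melanogaster. The probe table used here lists the first-generation Drosophila genome array. Per the labels' protocols, flies were kept at 25 °C, discs were dissected on ice, RNA was purified on spin columns, and biotin-labelled cRNA was made from 6 µg of total RNA. In 3 samples the 71B-Gal4 driver expressed a dominant negative form of the epidermal growth factor receptor Egfr, and in 3 it expressed an activated form. The arrays are called DN1 to DN3 and ACT1 to ACT3 here, by group and replicate number of the labels. The labels do not say that the replicates came from separate animals or cultures. The limma p-values therefore measure only the spread between these samples, which may be technical. No array of discs without a transgene was used here, so neither group is a baseline.

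The deposited table holds 1 log2 value per probe set and array. Per the submitters' processing notes the authors used GCRMA, which corrects the background by probe sequence and summarises the probes of a set. Its version and settings are not given in the sources used here. The log2 scale was read from the values, which ran from 4.72 to 15.08. Array medians lay between 8.01 and 8.06 and the SD over probe sets between 1.53 and 1.66, so the arrays do not share 1 distribution. No column was without a sample. Scanner files were not used here, so background and saturation flags per spot were not examined. The 4 yeast control probe sets, whose transcripts are not of the fly, averaged 5.54 to 5.96 per array and give a rough background level. The number of arrays limits the precision.

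Of 14010 probe sets, 44 control probe sets were left out and 13966 were tested. A filter at a mean log2 value of at least 4 removed 0 probe sets. The probe table gave 1 gene symbol for 12443 of the tested probe sets, several for 327 and none for 1196. Symbols were checked by Entrez identifier against a RefSeq gene table of assembly Release 6 plus ISO1 MT, which held 12394 of the single-symbol probe sets and changed 0 symbols. The genome build behind the array design is not given in the sources used here, so no coordinates are printed. Each of 10844 genes was represented by its probe set with the highest mean over the 6 arrays. Of these, 1209 genes had more than 1 probe set, and 674 of the 1599 other probe sets had a log2 difference of opposite sign to the one that represents the gene.

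The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, no covariate, two-sided), over probe sets and again over genes. P-values were adjusted by Benjamini-Hochberg, and a probe set or gene was called at an adjusted p under 0.05. A size limit of 2-fold was applied beside the test. Every log2 difference is activated minus dominant negative, with the standard error (SE) of the limma fit. An exact permutation test of 3 against 3 arrays cannot give a two-sided p under 0.1, so the limma fit, which pools the spread over genes, was used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

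Before the data were examined, 21 gene lists and 9 lists of cell type markers were fixed. They hold 393 names, of which 7 matched no single symbol; 299 distinct genes were measured. Each list was tested with camera at its preset inter-gene correlation of 0.01, which compares the list with all other genes, and adjusted over the 30 lists. At that preset, camera's p depends on the spread across genes and does not measure the spread between the arrays. Camera with an estimated correlation, whose p is limited by the number of arrays, was an alternative. So was fry, whose p tests whether a list's genes move, on balance, in 1 direction. The genes named were also fixed by rule: Egfr by every probe set, up to 12 called genes per direction without overlap between groups, all targets of Egfr and ERK signalling in the fixed list, and up to 4 called members of each other list or, where none was called, its 2 members of smallest p. The rule gave 61 genes. Further genes are said to be chosen after their values were seen.

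The alternatives were a stricter filter, median centring, quantile normalization, an intensity trend with a robust prior, array weights, a replicate block, the mean of a gene's probe sets, a stricter threshold, limma's treat, and leaving out each array in turn. A filter at a mean of 8, a residual component as a covariate, and lists without certain members were added after seeing the data. The residual component is the first principal component of what remains after the group means.

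The limma step was tested on simulated data for this comparison, with 13966 probe sets, 200 of them changed, in 5 draws. With independent noise it called 90.4% of the probe sets changed by 1 on the log2 scale and 99.8% of those changed by 2. With a component shared across probe sets of an array, as in these arrays, it called 66.6% (range 17 to 98) and 95.8%. Draws of that kind with no change gave 0 to 1654 calls, against 0 to 2 with independent noise. The Benjamini-Hochberg cutoff depends on how many probe sets change, so the shares called may be lower where fewer than 200 change.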

Results

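Egfr is the fly's epidermal growth factor receptor, and its signal through Ras and the kinase ERK patterns wing veins and the disc. To find genes that respond to it, wing disc RNA was compared between 3 arrays with an activated receptor (ACT1 to ACT3) and 3 with a dominant negative, signal-blocking receptor (DN1 to DN3). Both were expressed with 71B-Gal4, a driver line that switches on transgenes in a tissue pattern. The values are log2 probe set signals over 13966 probe sets. Pearson's r between arrays, taken across probe sets, which are not independent replicates, averaged 0.975 within groups and 0.977 between groups. The closest pairs, DN1 with ACT1 and DN3 with ACT3, joined arrays of different groups and both had an r of 0.991. The most distant pair was DN3 with ACT2, at 0.962.

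**Figure D1:**
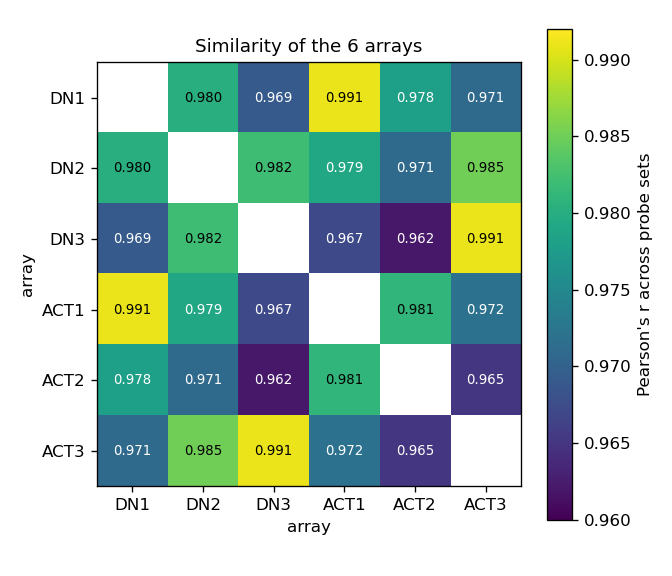
Pearson's r across probe sets between each pair of the 6 arrays, with the dominant negative arrays as DN1 to DN3, the activated arrays as ACT1 to ACT3, and the colour scale and printed numbers both giving r. The highest values, 0.991, join DN1 with ACT1 and DN3 with ACT3.

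The probe set that represents Egfr (142966_at) read 10.49 ± 0.29 (SD, n = 3) in activated discs and 8.97 ± 0.43 (SD, n = 3) in dominant negative discs. That is a log2 difference of 1.52 (SE 0.23), or 2.87-fold, with no overlap between the groups. It did not pass the limma threshold over all genes, with an adjusted p of 0.433, nor over all probe sets, with an adjusted p of 0.715. The other Egfr probe set (151735_at) had the opposite sign, with a log2 difference of -0.59 (SE 0.42) and overlapping groups (adjusted p = 1). It read 9.01 ± 0.66 in activated and 9.6 ± 0.81 in dominant negative discs (SD, n = 3 each). Leaving out 1 array moved its log2 difference between -1.06 and -0.33. With the mean of both probe sets the log2 difference was 0.47. Where either probe set lies relative to the transgenes is not known here, so neither checks the labels.

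Members of the list of transcriptional targets and feedback regulators of Egfr and ERK, called targets here for short, were together higher in activated discs. Not every member is known here to be switched on by the pathway. Of the 8 measured members, 7 were higher and 1 lower, with a mean log2 difference of 0.39 and a median of 0.35 (camera adjusted p = 6.33e-05). The adjusted p was 0.167 with an estimated correlation and 0.418 with fry, so the call was made by the preset form of camera alone. The estimated correlation was -0.02, not above the preset 0.01, so a higher correlation among the members was not why the call was lost. The preset form draws its p from the number of genes, while the estimated form is limited by the number of arrays. No member passed over all genes; adjusted over the list alone, 1 passed, sty (adjusted p = 0.00212). The gene sty encodes Sprouty, an intracellular inhibitor of receptor tyrosine kinase signalling, and read 9.92 ± 0.24 against 9.02 ± 0.13 (SD, n = 3 each). Its log2 difference was 0.90 (SE 0.16), a 1.87-fold difference without overlap. The log2 difference was 0.87 (SE 0.44) for kek1, a transmembrane inhibitor of the receptor, and 0.51 (SE 0.18) for aos, a secreted inhibitor of its ligands. The level of aos exceeded the mean of the yeast control probe sets, 5.54 to 5.96 per array, in ACT3 only (6.04). It read 5.19 ± 0.18 in dominant negative and 5.70 ± 0.31 in activated discs (SD, n = 3 each). A filter at a mean log2 value of 6, which leaves out aos, gave the list a mean of 0.37 (camera adjusted p = 0.000793). The log2 difference was 0.37 (SE 0.21) for spi, an activating ligand, and 0.33 (SE 0.13) for Mkp3, a phosphatase of ERK. The remaining members lay near 0: rau at 0.12 (SE 0.21), the ETS repressor gene aop at 0.08 (SE 0.32) and edl at -0.05 (SE 0.22). Leaving out 1 array moved the log2 difference of kek1 between 0.50 and 1.40 and that of spi between 0.20 and 0.56. The members pnt, rho, vn and Ptp-ER had no probe set under their name alone and were not analysed here.

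**Figure D2:**
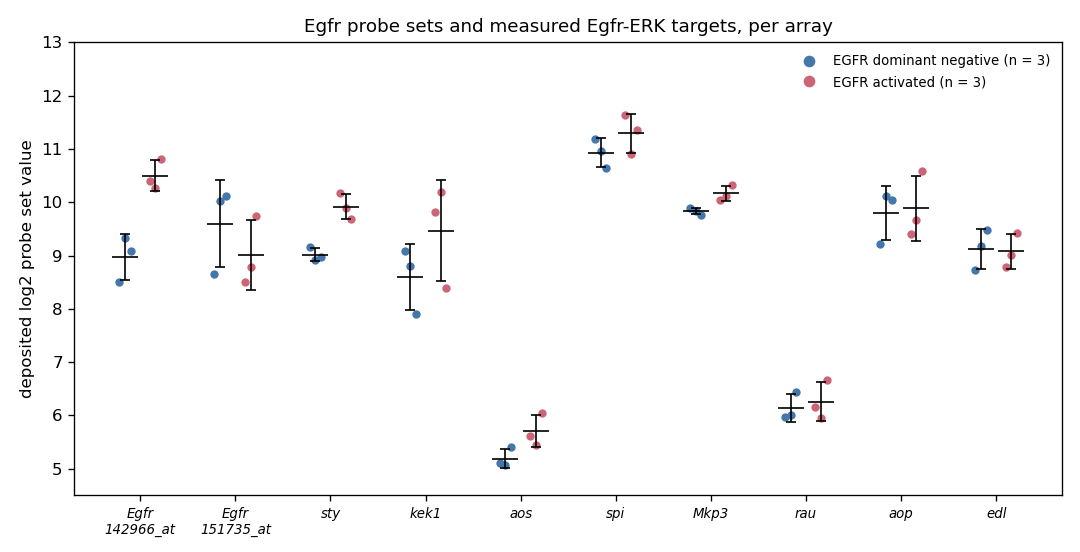
Deposited log2 value (vertical axis) of both Egfr probe sets and the 8 measured members of the list of Egfr-ERK targets and feedback regulators. Each point is 1 array, blue for dominant negative and red for activated discs (n = 3 each). A long bar gives the mean and whiskers the SD. The groups do not overlap for Egfr 142966_at or sty, while Egfr 151735_at, aop and edl overlap.

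Components of the Egfr, Ras and MAPK pathway were higher in activated discs by a mean of 0.20, with 11 of 16 measured members higher and 5 lower (camera adjusted p = 0.0202). With an estimated correlation the adjusted p was 0.65. Adjusted over the list alone, 1 member passed, Egfr itself (adjusted p = 0.00128). The next smallest p was that of Krn, a ligand gene, with a log2 difference of 0.30 (SE 0.14). Without Egfr, an alternative chosen after seeing the data, the mean was 0.11 and the adjusted p 0.193. The call also ended without DN1 (mean 0.12, adjusted p = 0.582), without ACT3 (0.17, 0.348), with array weights (0.12, 0.626) and with the mean of each gene's probe sets (0.14, 0.0504). With a filter at a mean log2 value of 8, added after seeing the data, the list mean was 0.36.

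Genes of the wing pouch and hinge, the parts of the disc that make the blade and its base, were higher in activated discs in 10 of 15 measured members and lower in 5. Their mean log2 difference was 0.13 and their median 0.21 (camera adjusted p = 0.0137; adjusted p = 0.312 with an estimated correlation). The members of smallest p were the zinc finger gene salm at 0.41 (SE 0.15) and the POU domain gene nub at 0.55 (SE 0.20), followed by salr at 0.41 (SE 0.15). The other probe sets of nub had 0.26 and 0.20, and the mean of all its probe sets had 0.34. The pouch selector gene vg had a log2 difference of -0.37 (SE 0.27). Leaving out 1 array moved vg between -0.66 and -0.15, and salr between 0.27 and 0.49. Adjusted over the list alone, 0 members passed. The call ended without DN1 (mean 0.05, adjusted p = 0.489), without ACT3 (0.06, 0.348) and with array weights (0.05, 0.399).

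Wing vein genes did not pass as a list with all 6 arrays, with a mean log2 difference of 0.16 over 9 members (camera adjusted p = 0.0773). The POU domain gene vvl, which is expressed in veins, was the 1 member that passed when adjusted over the list alone (adjusted p = 0.00428). It read 10.34 ± 0.20 in activated and 9.34 ± 0.33 in dominant negative discs (SD, n = 3 each), a log2 difference of 1.00 (SE 0.19) without overlap. The Iroquois gene caup had a log2 difference of 0.48 (SE 0.15), and aos, near background level, is also in this list. The list was called without DN2 (mean 0.22, adjusted p = 0.0023), without DN3 (0.21, 0.0453), without ACT1 (0.22, 0.0138) and without ACT2 (0.18, 0.0254). The mean was 0.04 without DN1, 0.08 without ACT3 and 0.05 with array weights, none of them called.

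Genes of cuticle and chitin were lower in activated discs: 13 of 18 measured members were lower and 5 higher, with a mean log2 difference of -0.23 and a median of -0.17 (camera adjusted p = 6.33e-05). With an estimated correlation the adjusted p was 0.167, and with fry it was 0.418. Adjusted over the list alone, 1 member passed, obst-B (adjusted p = 0.0134), which encodes a chitin-binding protein. It read 9.90 ± 0.28 in activated and 10.86 ± 0.29 in dominant negative discs (SD, n = 3 each), a log2 difference of -0.96 (SE 0.20). The chitin-binding protein gene Gasp differed by -0.92 (SE 0.27), the chitin deacetylase gene verm by -0.66 (SE 0.20) and the chitinase gene Cht5, named after its values were seen, by -0.49 (SE 0.16).

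Gasp, verm and serp were also fixed as tracheal markers, since air tubes attach to the wing disc. The tracheal list had a mean of -0.24 and a median of -0.07 over 7 members and was not called (camera adjusted p = 0.0694), while Gasp and verm passed when adjusted over the list alone (adjusted p = 0.0342 for both). The tracheal list was called with array weights (mean -0.32, adjusted p = 0.0178), without DN1 (-0.33, 0.014), without ACT3 (-0.34, 0.0311) and with the residual component, added after seeing the data (-0.24, 0.0124). Without the 3 shared genes, an alternative chosen after seeing the data, the 15 remaining cuticle and chitin genes had a mean of -0.15 (adjusted p = 0.0114, and 0.312 with an estimated correlation).

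Markers of 2 organs outside the disc, the salivary gland and the fat body, were lower in activated discs. All 7 measured salivary gland markers were lower, with a mean log2 difference of -0.62 and a median of -0.74 (camera adjusted p = 0.00143; adjusted p = 0.455 with an estimated correlation). Of these markers, Sgs1 at -0.03 (SE 0.18) and fkh at -0.02 (SE 0.19), named after their values were seen, hardly differed. The glue protein gene Sgs4 read 7.50 ± 0.20 in activated and 8.24 ± 0.56 in dominant negative discs (SD, n = 3 each). Its log2 difference was -0.74 (SE 0.25), and 0 members passed when adjusted over the list alone. The glue gene Sgs3 had a log2 difference of -1.21 (SE 0.59) and overlapping groups, and leaving out 1 array moved it between -1.97 and -0.73. It read 7.86, 10.34 and 9.95 in DN1, DN2 and DN3, and 7.51, 8.01 and 9.01 in ACT1, ACT2 and ACT3. The list also differed by 1.05 between DN1, ACT1 and ACT2 and the set of DN2, DN3 and ACT3, higher in the latter. This split does not follow the transgenes but is not balanced over them either, since DN2 and DN3 share a side. A difference along it can therefore enter the comparison of the groups, toward lower values in activated discs. Without DN3 the list was no longer called (mean -0.42, adjusted p = 0.0662), and the mean was -1.01 without DN1 and -0.98 with array weights.

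The 6 measured fat body markers had a mean of -0.42 and a median of -0.41, with 4 lower and 2 higher (camera adjusted p = 0.00803; adjusted p = 0.455 with an estimated correlation). Fbp2 passed when adjusted over the list alone (adjusted p = 0.008), at 7.97 ± 0.35 against 9.04 ± 0.41 (SD, n = 3 each) and a log2 difference of -1.07 (SE 0.24). Fbp1, which encodes a receptor for larval storage proteins, had a log2 difference of -0.71 (SE 0.30), and leaving out 1 array moved it between -0.90 and -0.34. The fat body call ended without DN3 (mean -0.25, adjusted p = 0.0865) and without ACT1 (-0.21, 0.123), and with array weights the mean was -0.65. Along the split of arrays given for the salivary gland list, fat body markers differed by 0.43, higher in the set with DN2 (camera adjusted p = 0.235). As for that list, this difference can also enter the comparison of the groups.

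**Figure D3:**
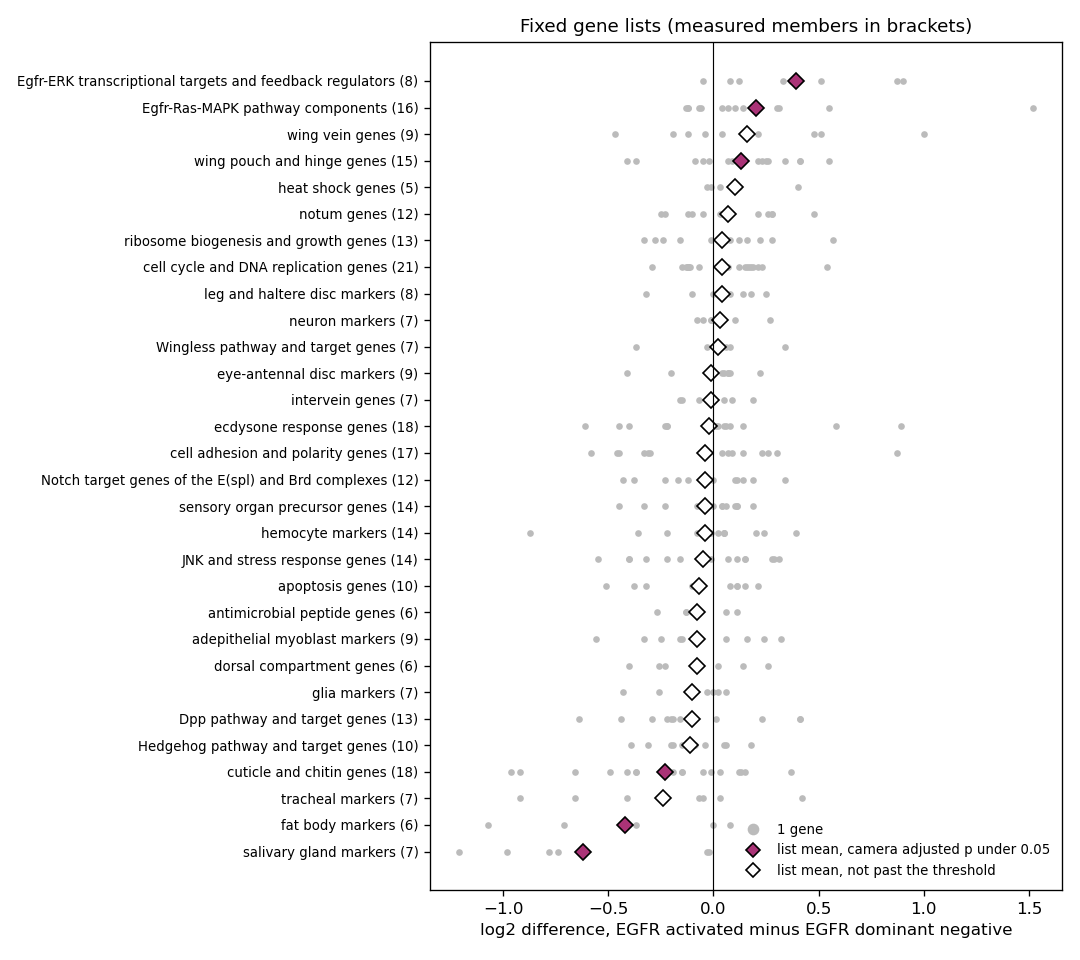
Log2 difference, activated minus dominant negative (horizontal axis), for the 30 fixed lists, with a grey point per measured gene and a diamond for the list mean, filled where camera's adjusted p is under 0.05. The 6 filled diamonds run from -0.62 for salivary gland markers to 0.39 for targets of Egfr and ERK, and none of these lists passes with an estimated correlation.

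Markers of the remaining cell types did not pass as lists, with all 6 arrays or under the alternatives run. Hemocyte markers, of blood cells, had a mean of -0.04 (camera adjusted p = 0.803), and SPARC passed when adjusted over the list alone (adjusted p = 0.0104). SPARC encodes a collagen-binding protein of basement membranes and had a log2 difference of -0.87 (SE 0.18), while the prophenoloxidase gene PPO2 had 0.39 (SE 0.16) at its main probe set and 0.09 at the other. Markers of adepithelial myoblasts, the muscle precursors under the notum, had a mean of -0.08 (adjusted p = 0.614), with Him at -0.56 (SE 0.18). The mean was -0.10 for glia (adjusted p = 0.56), 0.03 for neurons (0.803), -0.01 for eye-antennal disc markers (0.803) and 0.04 for leg and haltere disc markers (0.674).

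The remaining patterning and hormone lists did not pass with all 6 arrays, and some did without 1 array. Ecdysone response genes had a mean of -0.02 (camera adjusted p = 0.116), and Edg91, a hormone-dependent cuticle protein gene, passed when adjusted over the list alone (adjusted p = 0.0249) with a log2 difference of -0.61 (SE 0.14). The ecdysone early gene br had -0.45 (SE 0.19) at its main probe set, and its other probe sets had 0.37 and 0.54. At the main probe set, leaving out 1 array moved br between -0.57 and -0.26. The list mean was -0.01 for intervein genes (adjusted p = 0.843), 0.07 for notum genes (0.614) and -0.08 for dorsal compartment genes (0.916). It was -0.04 for sensory organ precursor genes (0.674) and -0.04 for Notch targets (0.803). Among the morphogen pathways the mean was -0.10 for Dpp (0.674), -0.11 for Hedgehog (0.614) and 0.02 for Wingless (0.803). Hedgehog was called without DN1 (mean -0.27, adjusted p = 0.014), without ACT3 (-0.31, 0.00958) and with array weights (-0.26, 0.0321), and Dpp without DN1 (-0.28, 0.0238). Notum genes were called without ACT1 (0.19, 0.018), and ecdysone response genes without DN3 (-0.18, 0.000672) and without ACT2 (-0.04, 0.0267).

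Lists of growth, death, stress, immunity and adhesion did not pass with all 6 arrays. The mean log2 difference was 0.04 for cell cycle and DNA replication genes (camera adjusted p = 0.614) and 0.04 for ribosome biogenesis and growth genes (0.803). It was -0.07 for apoptosis genes (0.674), where Debcl, a Bcl-2 family gene, had -0.38 (SE 0.16), and between -0.47 and -0.24 with 1 array left out. It was -0.05 for JNK and stress response genes (0.674), where the Fos gene kay had -0.55 (SE 0.18) at its main probe set and 0.05 at the other. The mean was 0.10 for heat shock genes (0.803), -0.08 for antimicrobial peptide genes (0.515) and -0.04 for cell adhesion and polarity genes (0.803). Without ACT2, cell cycle and DNA replication genes were called (mean 0.14, adjusted p = 0.00592), and so were heat shock genes, with the opposite sign (-0.33, 0.0321). Adjusted over the list alone, 0 members passed in the uncalled lists other than those of veins, trachea, hemocytes and the ecdysone response. In 6 of the 30 lists, all uncalled, the mean, the median and the test were not of 1 sign: sensory organ precursors, apoptosis, JNK and stress, hemocytes, neurons and eye-antennal disc.

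No single gene or probe set passed the limma threshold. Over 13966 probe sets 0 were called, also with the 2-fold limit, and the smallest adjusted p was 0.0949. At an unadjusted p under 0.05 there were 308 probe sets, 128 higher and 180 lower in activated discs, where chance alone gives 698. Over 10844 genes 0 were called, and 258 had an unadjusted p under 0.05 (98 higher, 160 lower, 542 by chance). These counts depended on the arrays: they ran from 193 probe sets without DN2 to 1043 without ACT3, and from 160 to 857 genes without the same arrays. With array weights they were 1109 probe sets and 946 genes, above the chance values. Where probe sets of an array move together, such counts can lie far from the chance value without a group effect. Under the main fit, the other splits of the arrays into 3 and 3, examined after the results were seen, gave 70 to 3801 such probe sets. The gene of smallest adjusted p, named after its values were seen, was CG13053 (adjusted p = 0.0521). It read 9.36 ± 0.15 in activated and 10.82 ± 0.21 in dominant negative discs (SD, n = 3 each), a log2 difference of -1.46 (SE 0.16). The groups did not overlap for 870 probe sets, or 6.23%, where chance gives 10%. A difference of at least 2-fold at any p was seen for 10 genes, 1 higher and 9 lower. The count of called genes was 1 (CG13053) with quantile normalization, with trend and robust prior, with array weights and with the mean of a gene's probe sets. It was 1 without DN1 (yip7), 3 without ACT3 (CG4382, Obp56a and CG13053) and 10 with a residual component as a covariate, which was added after seeing the data.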

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

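The filter at a mean of 8, the residual component, and the lists without Egfr or without shared members were chosen after seeing the data. The alternative without a filter removes nothing from the main setting, where 0 probe sets fell under the minimum, so it tests nothing. Over the alternatives run, the void one included, 37 counts stayed at 0. In the same runs, 1159 values of named genes and 460 list means kept their direction and their side of the threshold. Meanwhile 11 counts moved, and 15 values of genes and 40 of lists changed sign. Another 16 values of genes and 17 of lists came to pass the threshold under an alternative, and 23 of lists no longer passed it, counting each result once per alternative. Many kept directions were fixed in advance. The filters, trend and robust prior, replicate block and residual component cannot change a gene's log2 difference. Nor can the mean of a gene's probe sets where the gene has no other. The estimated correlation and fry reuse the same list means. The tally of kept directions therefore overstates how far they were tested. Background flags per probe set were not used here, and the yeast control probe sets, at 5.54 to 5.96, give only a rough level, which aos did not exceed in its group means. Having 3 arrays per group limits the precision.

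Called probe sets went from 0 to 1 with array weights (CG13053) and to 3 with the residual component (Egfr, CG4382 and CG13053), with or without the 2-fold limit. Called genes went from 0 to 1 (CG13053) with quantile normalization, with trend and robust prior, with array weights and with the mean of a gene's probe sets, and to 10 with the residual component. Leaving out 1 array gave 0 to 3 called genes, with 1 without DN1 (yip7) and 3 without ACT3 (CG4382, Obp56a and CG13053). The adjusted p of CG13053 ran from 0.00301 to 0.65. A threshold of 0.01 and treat at 1.2-fold gave 0. Unadjusted counts of 308 probe sets and 258 genes became 933 and 765 with the residual component, 1109 and 946 with array weights, and 518 and 439 without DN1. They ran from 193 to 1043 and from 160 to 857 with 1 array left out, and were 195 and 162 without ACT2.

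With an estimated correlation and with fry, all 6 called lists lost their call at unchanged means. The adjusted p were 0.167 and 0.418 for the targets of Egfr and ERK (mean 0.39) and for cuticle and chitin (-0.23), 0.65 and 0.81 for pathway components (0.20), 0.312 and 0.81 for pouch and hinge (0.13), and 0.455 and 0.81 for fat body (-0.42) and for salivary gland (-0.62). Array weights ended the call of components (0.12) and of pouch and hinge (0.05), the mean of a gene's probe sets that of components (0.14), and leaving out Egfr likewise (0.11). The targets and the cuticle list were called under each other alternative run, with camera adjusted p up to 0.0311 and 0.0138. Leaving out 1 array moved the mean of components between 0.12 and 0.27, of pouch and hinge between 0.05 and 0.18, of fat body between -0.54 and -0.21, and of salivary gland between -1.01 and -0.42.

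Uncalled lists were called under these alternatives: wing vein without DN2, DN3, ACT1 or ACT2, notum without ACT1, Dpp without DN1, Hedgehog without DN1 or ACT3 and with array weights, ecdysone without DN3 or ACT2, cell cycle and heat shock without ACT2, and tracheal with array weights, the residual component, or without DN1 or ACT3. Signs also changed for genes and lists not called in the main setting. Of the values that changed sign, heat shock without ACT2 was called (-0.33, camera adjusted p = 0.0321). With array weights aop went to -0.29, if to -0.06, Hsp68 to -0.10 and futsch to 0.03. With the mean of a gene's probe sets br went to 0.15 and stv to -0.02. Among lists, array weights gave -0.10 for notum, -0.07 for Wingless, -0.01 for cell cycle, 0.09 for ecdysone, -0.11 for heat shock and 0.05 for eye-antennal disc. The mean of a gene's probe sets gave 0.02 for ecdysone. The filter at 8 gave 0.03 for Notch targets, 0.04 for ecdysone, 0.02 for cell adhesion and polarity and 0.02 for eye-antennal disc. Leaving out 1 array gave ranges from -0.27 to 0.32 for aop, -0.08 to 0.28 for rau, -0.25 to 0.12 for edl, -0.05 to 0.28 for stv, -0.63 to 0.97 for Hsp68, -0.19 to 0.01 for futsch and -0.48 to 0.03 for nrv2. For list means the ranges were -0.08 to 0.08 for intervein, -0.04 to 0.19 for notum, -0.25 to 0.02 for dorsal compartment, -0.12 to 0.09 for Notch targets, -0.28 to 0.01 for Dpp, -0.31 to 0.02 for Hedgehog and -0.06 to 0.13 for Wingless. They were -0.07 to 0.14 for cell cycle, -0.13 to 0.01 for apoptosis, -0.02 to 0.10 for ribosome biogenesis, -0.18 to 0.08 for ecdysone, -0.33 to 0.37 for heat shock, -0.14 to 0.05 for cell adhesion, -0.05 to 0.15 for neurons and -0.05 to 0.03 for eye-antennal disc. Apart from the fewer genes or arrays that some of these alternatives hold, the cause was not tested.

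Replicate numbers recur in both groups, and a replicate block left the counts at 0 probe sets and 0 genes (774 and 615 unadjusted) and the 6 lists called, with tracheal markers added (adjusted p = 0.0233). Over all probe sets, the numbers paired only some of the arrays. Deviations from the group means correlated at 0.61 and 0.60 for numbers 1 and 3, whose arrays matched each other best. For number 2 the correlation was -0.08, and DN2 and ACT2 each matched an array of another number best. Some heat shock genes, examined after their values were seen, were nonetheless highest in DN2 and ACT2. Hsp68 read 9.33 and 10.79 there and 7.59 to 8.04 in the others, and DnaJ-1 and Hsp26 were also highest there. Hsp27 and stv were not. Whether the arrays of number 2 were handled together is not known here. The main fit held no block, so any spread shared by a replicate number stays in its SE.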

Other observations

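The genes named in the next paragraph, ImpE1 and Lsp2 further on, the comparison of 5′ and 3′ control signal, the counts of calls in other splits, and the fits with a residual component were chosen only after the results were seen.

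Outside the fixed lists, the genes of smallest p that were higher in activated discs included 2 with known links to extracellular or receptor signalling. The heparan sulfate sulfatase gene Sulf1 read 9.73 ± 0.28 against 9.12 ± 0.13 (SD, n = 3 each), a log2 difference of 0.61 (SE 0.17). The ankyrin repeat gene mask, a known modifier of receptor tyrosine kinase signalling, had 0.63 (SE 0.17) at its main probe set and 0.25, 0.20 and 0.04 at its others. Upf1, a helicase of nonsense-mediated decay, had 0.58 (SE 0.14). Genes of smallest p that were lower in activated discs included 2 that encode secreted proteins. The odorant-binding protein gene Obp56a read 9.02 ± 0.50 against 10.06 ± 0.15 (SD, n = 3 each), a log2 difference of -1.04 (SE 0.23). The superoxide dismutase gene Sod3 had -0.89 (SE 0.20) at its main probe set, and its other probe sets had -0.34 and 0.19. CG4382 had -1.30 (SE 0.27), CG31075 -1.08 (SE 0.17) and Ypel -0.66 (SE 0.14). None passed the limma threshold over all genes, and no theme was tested among them.

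The strongest division among the arrays did not follow the transgenes, though its sets hold unequal numbers of arrays of each group. Among the 10 splits of the 6 arrays into 3 and 3, the one that sets DN1, ACT1 and ACT2 against DN2, DN3 and ACT3 called 982 probe sets, 735 higher and 247 lower in the set without DN1. The real comparison called 0. The tables argue against unequal widths of the arrays' distributions, since quantile normalization left 927 calls. They also argue against gene length (gene span, introns included, known for 99.6% of genes): removing each array's trend left 825 of 875 genes called. A difference in 5′ to 3′ signal of the control transcripts cannot be told apart from other causes, since the sets differed by 0.22 with overlapping ranges, and the overlap was lost when 1 array was left out. An unlabelled batch or the age of the larvae may also stand behind the division. Neither was tested, and no biological explanation was tested.

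Other values moved along this division or between arrays. Salivary gland markers were higher by 1.05 in the set without DN1 (camera adjusted p = 0.000181; adjusted p = 0.316 with an estimated correlation), and the Dpp and Hedgehog lists were each higher by 0.52 (adjusted p = 6.55e-05 and 2.67e-05; 0.248 and 0.316 with an estimated correlation). Cell cycle and DNA replication genes were higher by 0.22 there (adjusted p = 0.00289; adjusted p = 0.524 with an estimated correlation). The other lists called between the groups were not called along this division. The division is not independent of the groups, so a difference along it can still enter their comparison. Their differences, as the set without DN1 minus the other, were 0.43 for fat body markers (camera adjusted p = 0.235) and 0.21 for cuticle and chitin (0.0539). They were 0.14 for pouch and hinge (0.302), 0.08 for pathway components (0.136) and -0.05 for targets of Egfr and ERK (0.561). The hormone-induced gene ImpE1 read 10.44, 9.99 and 8.19 in DN1, DN2 and DN3, and 11.42, 10.76 and 9.10 in ACT1, ACT2 and ACT3. The 3′ control probe set of 18S ribosomal RNA read 12.8, 10.13 and 6.81 in the dominant negative arrays and 11.97, 6.93 and 6.85 in the activated arrays, in the order of their numbers. The storage protein gene Lsp2 read 10.74, 11.05 and 12.35, and then 9.90, 10.88 and 12.02, in the same order.

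With the residual component as a covariate, 10 genes were called: Egfr, sty, CG4382, Obp56a, Phk-3, CG31075, CG13053, obst-B, CG1572 and Gasp. The SE of Egfr, at a log2 difference of 1.52, went to 0.15 (limma adjusted p = 0.00301). That of sty, at 0.90, went to 0.13 (adjusted p = 0.0316). The component is taken from the residuals of the same fit, so it shrinks them by construction. It also cannot change a log2 difference, so the unchanged differences test nothing. Other splits also gained calls with it, up to 1426 genes, and 76 in the split of DN1, DN2 and ACT1 from the rest.

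The lower cuticle and chitin list may come in part from a smaller share of tracheal cells in activated samples, which is a hypothesis. The members outside the tracheal list had a mean of -0.15 (SE 0.08 over the member genes, not of the limma fit), while the whole list had -0.23. The rule written for this test asked for a mean below -0.12, the midpoint between 0 and the mean of the whole list. It also asked that these members pass camera and that the remaining tracheal markers not be clearly lower. These conditions for arguing against tracheal cells were met (camera adjusted p = 0.0114, and 0.312 with an estimated correlation). The mean, however, lay below -0.12 by less than its SE. This comparison was not part of the rule, and an SE over genes does not measure the spread between arrays. The 4 tracheal markers outside the cuticle list had a mean of 0.08 (SD 0.23), where a smaller share would lower them. Because the margin to -0.12 lies within the SE, the values do not decide. A change in tracheal share and a change in expression cannot be told apart for this list.

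Splits of 3 against 3 arrays number 10, too few for a share under 0.05. All 10 splits gave at least the real count of 0 called probe sets and 0 called genes. No count can lie below 0, so this outcome was fixed in advance and tests nothing. The highest others were 982 and 875. For the targets of Egfr and ERK, 1 of the 10 splits, the real one, reached a camera p of 3.87e-06, and the smallest other was 0.0056. For cuticle and chitin genes it was also 1 (4.22e-06 against 0.0023), and for fat body markers 1 (0.00107 against 0.00694). For pathway components 2 splits gave a p as small (0.00404 against 8.31e-06), for wing pouch and hinge genes 2 (0.00229 against 0.000743), and for salivary gland markers 3 (0.000143 against 1.81e-05).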
